A study of Mus musculus with 2 samples.

How the data were processed

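Single-cell RNA of the arcuate nucleus and median eminence of adult mice was measured by Drop-seq, which captures cells with barcoded beads in droplets and reads the 3' ends of transcripts. Per the labels, there were 2 libraries. The wild type library pooled 7 mice and the Irx3/5 double heterozygote library pooled 5 mice, all of the CD-1 strain. Live cells were sorted before capture, per the labels' protocols. Each library counted as 1 sample, because nothing maps cells to single mice.

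The deposited table of each library holds whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, made by the authors before deposit. The submitters' processing notes name bcl2fastq, Picard, STAR 2.6.0b, Seurat 3 and the mouse genome build mm10. The gene annotation and the setting for reads that match several gene copies are not given in the sources used here. A merged table deposited by the authors holds the natural log of 1 plus counts per 10000 UMIs of each cell, as its values show. It kept 4297 of the 4600 barcodes, almost exactly those with over 200 and under 5000 genes and under 10% mitochondrial UMIs. It served only as an alternative set of cells.

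The wild type table held 2800 barcodes with 4426817 UMIs and the double heterozygote one held 1800 barcodes with 2974060 UMIs. The median was 1059 UMIs per barcode in wild type and 936.5 in the double heterozygote. Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 395 and 316 barcodes. Doublets were called in each library with Scrublet (scanpy 1.11.5, expected rate 5%) and left out. The caller marked 17 of 3889 cells (0.437%), far under the expected rate, so the used cells may still hold doublets. The 3872 used cells were 2392 wild type cells with a median of 1274 UMIs and 1480 double heterozygote cells with a median of 1156.5 UMIs.

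Both libraries were clustered together. Counts were scaled per cell and log transformed, 30 principal components of 2000 variable genes were computed, and Leiden clustering (leidenalg 0.10.2) at resolution 1 was run on a graph of 20 neighbours. Irx3, Irx5, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes were left out of the variable genes. This gave 22 clusters. Clusters were named as "like" a cell type from marker genes fixed before the data were examined. A name needed at least 3 markers found in 10% of the cluster's cells at over 2 times the level of the median cluster, a mean marker score of at least 2, and a score at least 0.6 times that of the best cluster of the class. These limits were set after the data were seen. Where several classes passed, the class with the most markers among the cluster's top 10 genes was taken, a step added after 2 alternative settings had placed the larger tanycyte cluster among astrocytes. It left the names of the main clustering as they were. The limits kept 1 cluster unnamed, with 1.88% of wild type and 2.36% of double heterozygote cells. No cluster was named neuroblast-like. A class was to be compared as a whole only if none of its clusters had more markers of another class than of its own among its top 10 genes. Clusters 1 and 19 of the neuron-like class (236 wild type and 227 double heterozygote cells together) did not meet this. Each had 1 fixed neuroblast marker there, Dlx1 or Nhlh2, and no pan-neuronal marker, although both passed the neuron markers. These genes also stand on the fixed list of arcuate transcription factors, and cluster 19 was led by fixed neuron subtype markers such as Kiss1. Their shares are given by cluster number, and the main neuron values are given with and without them. This was chosen after the data were seen.

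UMIs were summed per library and cell class. Classes with at least 100 cells in each library were compared, which held for 4 classes. Levels are CPM, the usual scaling of a gene's counts by the total UMIs of the class. Log2 ratios are double heterozygote over wild type, so a value above 0 is higher in the double heterozygote library. Ratios carry exact conditional binomial intervals, counts exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and all for counting error only. No p-values are given, because there is 1 pool per genotype and cells are not replicates. Where a library held 0 counts, the fold is a bound against a floor of 3 counts in that library and class.

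The 35 gene lists were fixed before the data were examined. A list's value is the median log2 ratio over its members with at least 10 UMIs in the class, with 0.5 added to each sum. Lists with under 5 such members are given as single genes only. Each median is set among 10000 random lists of the same size, drawn from 20 bins of mean expression, and its percentile describes these libraries only. The range beside a median is the 95% range over 1000 Poisson redraws of the counts, shifted to centre on the observed median. The shift was chosen after some ranges without it had left out their own medians. Named genes were ranked by the interval bound nearest to 0 among genes with at least 30 UMIs in the class, without mitochondrial, ribosomal protein, haemoglobin and sex-linked genes. The rule took 12 genes per direction in neurons and tanycytes and 5 per direction in the other classes. Members of the fixed lists were also named as examples. Single values of a few of these genes are not reported here. Because many genes named by this rule differed alike in every class, a second ranking was made after the data were seen. It took protein-coding genes whose interval in the class excluded 0 and whose interval in all other cells did not lie on the same side of 0, without genes that have a pseudogene copy named after them. Genes with over 50% of their UMIs in a single cell of the library with the higher level were left out.

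Shares of neurons with a UMI of a gene were compared after every cell was thinned at random to 1000 UMIs. Shallower neurons were left out, 303 in wild type and 231 in the double heterozygote. The tests of explanations on suprachiasmatic markers, on pseudogenes and on Agrp against other peptides used another random draw. Oligodendrocyte-like cells treated in the same way gave the background from free RNA. Gene types and positions came from GENCODE mouse release 21 (GRCm38, the assembly behind mm10), which matched 93.3% of 29809 gene names. Computations used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

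The scripts were tested on simulated counts with the depths of the neurons. Among 10344 genes the 95% intervals held the true ratio in 96.1%, and 4.20% of 10084 genes made without a difference had an interval that excluded 0. Of 50 genes each, the interval lay on the right side of 0 for 96% at a 0.25-fold level, 88% at 0.5-fold, 92% at 2-fold and 100% at 4-fold. Of 200 lists made without a difference, 4% fell outside percentiles 2.5 to 97.5, and 97% of the ranges held the true median. The simulation had sampling noise only, with no spread between mice or preparations.

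Other settings chosen before the data were examined were a minimum of 500 genes per cell, doublets kept, no mitochondrial limit, resolution 2, classes from each cell's own marker score, each library clustered alone, the cells of the merged table, other scalings, the mean over cells, 2 added to each sum, higher count minimums and other thinning. Settings added after seeing the data were cells with at least 1000 UMIs, neurons without their cluster of lowest UMI counts or without the clusters led by a neuroblast marker, all cells without neurons, pseudogenes left out, and naming without the leading genes.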

Results

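Cells of the arcuate nucleus and median eminence, hypothalamic tissue that controls feeding and growth, were compared between wild type mice and mice heterozygous for both Irx3 and Irx5, 2 Iroquois transcription factors. The series title names postnatal neurogenesis and leptin sensitivity as its subject. Each genotype was 1 pooled library, with 4255875 UMIs in 2392 used wild type cells and 2850978 UMIs in 1480 used double heterozygote cells. A median of 867.5 genes per cell was found in wild type and 779.5 in the double heterozygote. Pairs of values give wild type first. No difference has a replicate check, and each interval covers counting error only.

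Irx3 and Irx5 were both read at a lower level in the double heterozygote library, but with so few UMIs that an equal level was not excluded. Irx3 (ENSMUSG00000031734, minus strand of chromosome 8 from 91798525 to 91802067 in GRCm38) had 30 UMIs in wild type and 15 in the double heterozygote. This was 7.05 CPM (4.76 to 10.1) against 5.26 CPM (2.94 to 8.68), a fold of 0.746 (0.373 to 1.43). Irx5 (ENSMUSG00000031737, plus strand of chromosome 8 from 92357625 to 92376286) had 16 and 6 UMIs, or 3.76 CPM (2.15 to 6.11) against 2.10 CPM (0.772 to 4.58), a fold of 0.56 (0.179 to 1.51). Ependymal-like cells, which line the third ventricle, held 17 wild type and 4 double heterozygote UMIs of Irx3 and 8 and 4 of Irx5. Their CPM was 86.1 and 38.4 for Irx3 (fold 0.446, 0.109 to 1.37) and 40.5 and 38.4 for Irx5. In oligodendrocyte precursors Irx3 went the other way, with 8 and 4 UMIs or 32.5 and 73.8 CPM (fold 2.27, 0.5005 to 8.48), and Irx5 had 4 and 0 UMIs. Neuron-like cells held 0 and 1 UMIs of Irx3 and 2 and 0 of Irx5. With neurons left out, an alternative added after the data were seen, the folds were 1.15 (0.562 to 2.23) and 1.05 (0.332 to 2.92). The deleted part of each gene is not given in the sources used here, and a 3' tag outside it would be read from both alleles, so these counts check neither label.

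**Figure D1:**
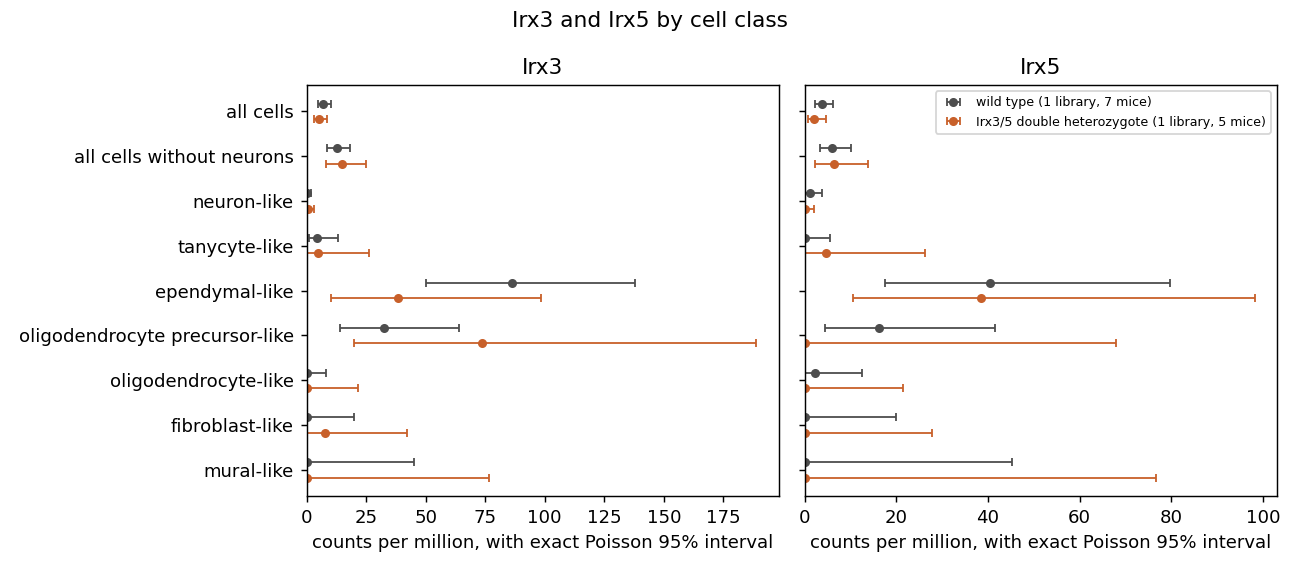
Level of Irx3 and Irx5 in each library (horizontal axis, CPM of the class) by cell class, with bars for the exact Poisson 95% interval. The ependymal-like values of 86.1 and 38.4 CPM for Irx3 have overlapping intervals.

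Neuron-like cells made up a larger share of the double heterozygote library, and tanycyte-like, oligodendrocyte-like and oligodendrocyte precursor-like cells a smaller one. Neurons were 34.4% (32.5 to 36.4) of wild type and 47.7% (45.1 to 50.3) of double heterozygote cells, a ratio of 1.38. Without clusters 1 and 19 they were 24.6% (22.9 to 26.4) and 32.4% (29.98 to 34.8), a ratio of 1.32 (1.16 to 1.49). Cluster 1 alone held 9.16% and 13.8%. Oligodendrocyte precursors, the dividing cells that give rise to myelinating glia, were 8.78% (7.68 to 9.99) and 3.99% (3.05 to 5.11), a ratio of 0.454. Among cells other than neurons it was 0.569 (0.419 to 0.763). It was 0.266 among cells with at least 1000 UMIs, a limit that left out 93 of 210 wild type and 41 of 59 double heterozygote precursors. Tanycytes, radial glia of the ventricle floor with stem cell properties, were 16.3% (14.8 to 17.8) and 11.2% (9.65 to 12.9), a ratio of 0.688. Among cells other than neurons the tanycyte ratio was 0.862 (0.715 to 1.04). It was 0.983 and 1.02 under 2 settings that named clusters without their leading genes, where the larger tanycyte cluster passed as astrocyte-like. Oligodendrocytes were 10.9% (9.65 to 12.2) and 8.31% (6.95 to 9.84), but among cells other than neurons their ratio was 0.958 (0.767 to 1.19). Microglia were 4.43% (3.64 to 5.33) and 3.11% (2.28 to 4.12). No cluster was named microglia-like with at least 500 genes per cell, nor in the double heterozygote library clustered alone. Fibroblasts were 6.48% (5.53 to 7.54) and 8.31% (6.95 to 9.84), with overlapping intervals, and mural cells were 3.05% and 3.92%. Fibroblast shares were 7.01% and 7.48% with at least 500 genes per cell, and 5.97% and 6.41% among cells with at least 1000 UMIs. No difference in their share of all cells is read from these values. Among cells other than neurons the fibroblast ratio was 1.61 (1.26 to 2.05). The mural order is not read as a difference, since it was 3.04% and 2.98% with at least 500 genes per cell and 2.81% and 2.02% among cells with at least 1000 UMIs. Ependymal-like cells were 5.73% and 4.93%, pars tuberalis-like cells 3.76% and 2.97%, and endothelial-like cells 1.67% and 0.878%. Median UMIs per cell differed within classes, with 1569.5 and 1770 in neurons, 1457 and 978.5 in tanycytes and 1065.5 and 760 in oligodendrocyte precursors. Shares can also be set by the dissection and the sort for live cells.

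**Figure D2:**
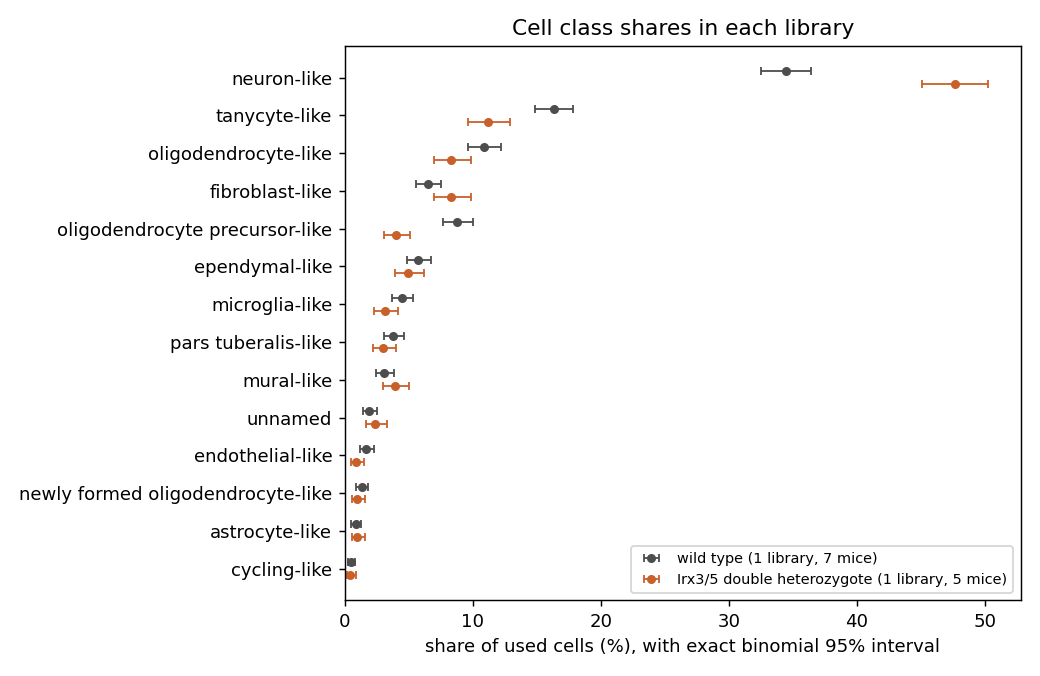
Share of used cells (%) in each named class, by library, with bars for the exact binomial 95% interval. Neuron-like cells stand at 34.4% in wild type and 47.7% in the double heterozygote, with the clusters 1 and 19 included.

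The appetite-stimulating peptides Agrp and Npy were read at higher levels in double heterozygote neurons, while the fixed list of energy balance peptides went both ways. Agrp had 335 UMIs in wild type and 1358 in the double heterozygote, a log2 ratio of 2.04 (1.86 to 2.22), and Npy 823 and 4002, a log2 ratio of 2.30 (2.19 to 2.41). Some alternatives left these intervals but kept the direction. Agrp was 2.54 with the mean over cells, 2.48 in the cells of the merged table, and 1.84 with own marker scores. Npy was 2.70 with the mean over cells and 2.16 with own marker scores. The Agrp UMIs lay in 22 wild type and 68 double heterozygote neurons, with 19.7% and 12.2% of them in 1 cell. Ghrh, the growth hormone-releasing hormone, had 39 and 197 UMIs (2.36, 1.85 to 2.89), and galanin (Gal) 530 and 1596 (1.61, 1.47 to 1.75). Without clusters 1 and 19 these log2 ratios were 2.04 for Agrp, 2.30 for Npy, 2.29 for Ghrh and 1.60 for Gal. Of the wild type Ghrh UMIs 37 lay in 1 cell, and the mean over cells gave 3.04 for this gene. Cartpt, a peptide that lowers food intake, was higher as well, with 3582 and 6974 UMIs (0.98), and 0.91 without those clusters. Pomc, the melanocortin precursor that lowers food intake, depended on them, with a log2 ratio of 0.45 over all neurons and 1.69 (1.55 to 1.83) without them. A single wild type cell of cluster 1 held 465 of the 1289 wild type Pomc UMIs, against 1743 UMIs in all double heterozygote neurons. Lower peptides were Vip, a signal of the suprachiasmatic clock (1273 and 284 UMIs, 118 of the latter in 1 cell, -2.15, -2.34 to -1.96), Trh (171 and 71, -1.25), Cck (332 and 158, -1.05) and Nts (78 and 42, -0.87). Sst had 2025 and 1735 UMIs (-0.20), but 509 of the wild type UMIs lay in 1 cell, so no direction is read from them. The list had 10 members higher and 9 lower, and its median of 0.27 (-0.06 to 0.53) stood at percentile 99.9 of matched lists. It was 0.00 (-0.19 to 0.23), at percentile 35.6, without clusters 1 and 19, and -0.13 when each cell was classed by its own marker score. Several of these genes led 1 of the 7 neuron-like clusters each (Agrp and Npy; Gal, Cartpt and Trh; Vip; Nts). The sums over all neurons do not separate the number of such cells from the level within each, and clusters defined by these genes do not either. With Agrp and Npy left out of the clustering, the neuron subcluster named by the markers of Agrp neurons was not larger in the double heterozygote library, at 7.16% (5.50 to 9.14) and 5.67% (4.08 to 7.64) of neurons. It was led by Klf4 and Rrad, with the stress genes Dnajb1 and Hspa1a among its top genes, so its share does not count Agrp neurons. With Agrp and Npy kept, the subcluster that these genes led held 2.06% (1.21 to 3.28) and 6.37% (4.69 to 8.44) of neurons. That size depends on the genes that differ, so it does not settle the number of such cells.

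The share of neurons with a UMI of Agrp, Npy, Gal or Cartpt was also higher in the double heterozygote library once each neuron was thinned to 1000 UMIs. Of 521 wild type and 475 double heterozygote neurons, 2.88% (1.62 to 4.70) and 9.05% (6.63 to 12.0001) had Agrp, and 4.22% (2.66 to 6.32) and 12% (9.22 to 15.3) had Npy. In counts these were 15 and 43 neurons with Agrp and 22 and 57 with Npy, against 15 and 41 and 27 and 50 in another random draw of the thinning. Gal was found in 5.18% (3.44 to 7.45) and 15.2% (12.1 to 18.7), and Cartpt in 20.3% (17.0 to 24.1) and 31.6% (27.4 to 36.0). Thinned oligodendrocytes, which should lack these peptides, had background shares of 1.23% and 1.28% for Agrp and Npy, 0.613% and 1.28% for Gal, and 4.91% and 6.41% for Cartpt. For Agrp and for Npy the background was 2 of 163 and 1 of 78 cells (0.149 to 4.36 and 0.0325 to 6.94), so it is known only roughly. The oligodendrocyte median before thinning was 1303 and 1126 UMIs per cell, against 1569.5 and 1770 in neurons. Trh went the other way, in 5.76% (3.92 to 8.12) of wild type and 1.89% (0.870 to 3.57) of double heterozygote neurons. Pomc was found in 4.99% and 6.11%, a difference not detectable at this depth. Sst was found in 7.68% and 12%, against the direction of its CPM, so no order is read from it. Ghrh in 0.384% and 1.89% and the leptin receptor Lepr in 0.384% and 0.842% lay near the background. Slc32a1, which loads GABA into vesicles, was found in 14.8% and 13.3%, and Slc17a6, which loads glutamate, in 15.2% and 13.5%. Hcrt and Pmch, peptides of the lateral hypothalamus, had no UMI in thinned neurons, which limits neurons with a UMI at this depth, not neurons that express them, to 0.706% and 0.774%. Without thinning Hcrt was found in 0.121% and 0% and Pmch in 0.243% and 1.42%. Without clusters 1 and 19, Agrp was found in 3.70% (2.09 to 6.04) and 11.1% (8.13 to 14.7) and Npy in 4.94% and 14.6%, Gal in 4.94% and 15.6% and Cartpt in 21.2% and 33.3%. The shares without thinning were 2.67% and 9.63% for Agrp, 5.22% and 15.2% for Npy, 7.52% and 18.0% for Gal, 24.8% and 38.8% for Cartpt and 8.74% and 11.9% for Pomc. Trh without thinning was found in 7.16% (5.50 to 9.14) and 4.67% (3.24 to 6.50), with overlapping intervals.

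**Figure D3:**
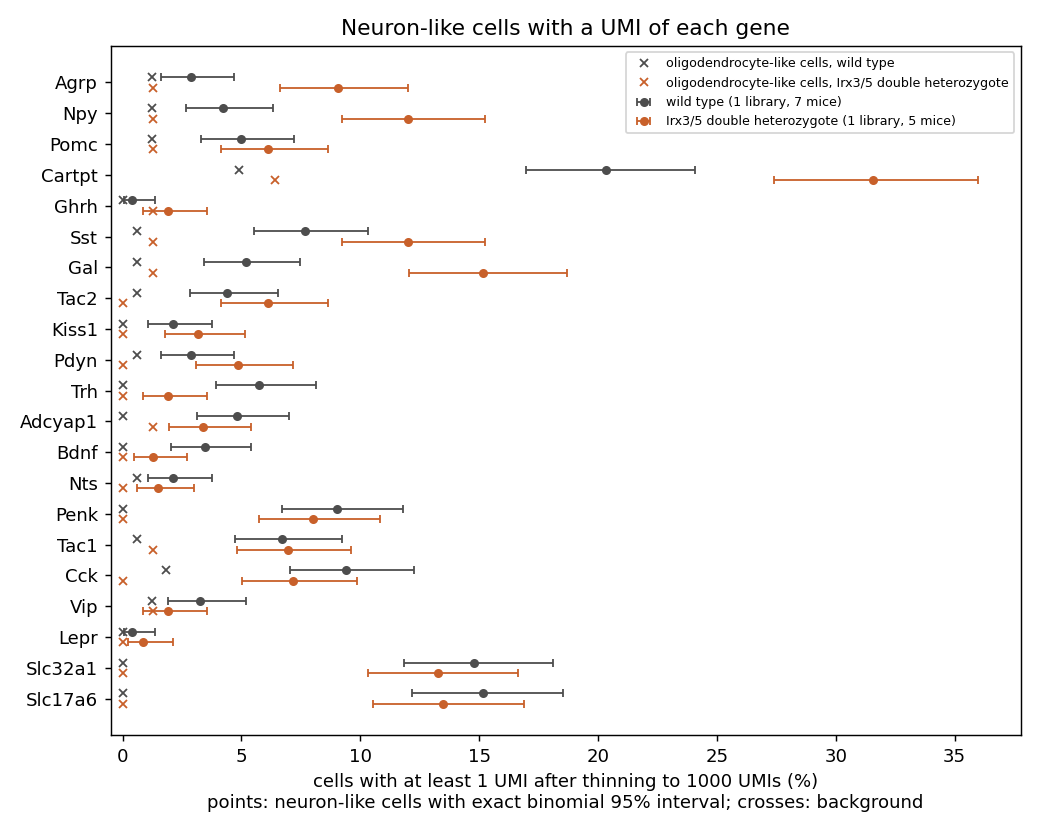
Share of neuron-like cells (%) with at least 1 UMI of each gene after thinning to 1000 UMIs, by library, with exact binomial 95% intervals; crosses give the share in oligodendrocyte-like cells. Npy stands at 4.22% in wild type and 12% in the double heterozygote, over a background of 1.23% and 1.28%, which rests on 2 of 163 and 1 of 78 cells.

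Receptors for energy balance signals were higher in double heterozygote neurons, arcuate transcription factors went both ways, and immediate early genes, which respond to activity and to cell dissociation, were lower. Of the receptors, 10 were higher and 3 lower, with a median log2 ratio of 0.54 (0.20 to 0.86) at percentile 99.97, and 0.75 (0.38 to 1.09) without clusters 1 and 19. The mix of neuron-like clusters differed between the libraries, and some receptors, such as Npy1r and Ghr, were among the leading genes of single neuron subclusters, so this median does not separate the mix of neurons from the level within each either. Examples were the melanocortin receptor Mc3r (6 and 26 UMIs, 2.13), the neuropeptide Y receptors Npy1r (47 and 107, 1.21) and Npy5r (11 and 32, 1.56) and the growth hormone receptor Ghr (19 and 39, 1.06). The serotonin receptor Htr2c was lower (41 and 18, -1.17). Among arcuate transcription factors 9 were higher and 6 lower (median 0.19, 0.00 to 0.45, percentile 96.8), and 8 higher and 7 lower without clusters 1 and 19 (0.19, -0.09 to 0.42). Otp had 47 and 119 UMIs (1.36), Gsx1 11 and 28 (1.37) and Tbx3 124 and 200 (0.71). Leptin signalling genes went both ways, with 9 higher and 6 lower and a median of 0.06 (-0.20 to 0.27). That median was 0.26 (0.00 to 0.46) without clusters 1 and 19 and -0.20 with the mean over cells. Lepr had 16 and 20 UMIs (0.34), the kinase Jak2 34 and 18 (-0.90) and Stat3 100 and 110 (0.16). Of the immediate early genes 2 were higher and 18 lower, with a median of -0.47 (-0.61 to -0.32), and of -0.42 (-0.60 to -0.27) without those clusters. Fos had 1323 and 872 UMIs (-0.58), Fosb 312 and 138 (-1.16) and Nr4a1 146 and 57 (-1.34).

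Genes of neurogenesis and immature neurons had 10 members higher and 8 lower in double heterozygote neurons, with a median of 0.09 (-0.06 to 0.28) at percentile 83.8. Without clusters 1 and 19 there were 9 higher and 9 lower, with a median of 0.024 (-0.15 to 0.22). The microtubule regulator Stmn1 had 314 and 581 UMIs (0.91) and Cd24a 29 and 59 (1.04), while Dcx, a marker of newborn neurons, had 34 and 36 (0.10) and Sox11 151 and 120 (-0.31). The 3 members also used to name neurons aside, the median was 0.10. No cluster was named neuroblast-like, and the cycling cluster held 11 wild type and 6 double heterozygote cells. Single GABA and glutamate genes differed little or went apart, such as Gad1 (446 and 431 UMIs, -0.03), Gad2 (787 and 898, 0.21) and Slc17a6 (426 and 327, -0.36). Synaptic vesicle genes had a median of 0.00 and neurotransmitter receptors of 0.04, or -0.097 with the mean over cells. Nuclear genes of oxidative phosphorylation were higher in 20 of 22 members (median 0.23, 0.19 to 0.27). The median was 0.36 with the mean over cells, and 0.19 with own marker scores, without the neuron cluster of lowest UMI counts and with pseudogenes left out. Coding genes with a pseudogene copy named after them were higher in neurons as well, with a median of 0.19 (0.16 to 0.22). The rise is therefore not read as particular to oxidative phosphorylation. Mitochondrially encoded genes had a median of -0.41, which was -0.17 (-0.33 to 0.07) without the neuron cluster of lowest UMI counts, an added alternative. Ribosomal protein genes had a median of -0.53. This list took genes by name, and 249 of its 351 entries were pseudogenes, among them 202 of the 300 measured in neurons. With pseudogenes left out, an alternative added after the data were seen, the median was 0.19. Over all cells, processed pseudogenes had a median of -0.73 and took 8.42% of wild type and 5.73% of double heterozygote UMIs. Heat shock genes had a median of 0.19 (0.13 to 0.25), cholesterol synthesis genes of 0.09, glycolysis genes of 0.05 (0.20 with the mean over cells), and unfolded protein response genes of -0.02. Myelin genes had a median of -0.39 (-0.65 to -0.14) at percentile 5.37, and tanycyte subtype genes of -0.50 (-0.90 to -0.10) at percentile 9.11, which was 0.026 over members with at least 30 UMIs. Astrocyte function genes had -0.38 (-0.69 to -0.18) at percentile 0.705, but -0.09 with at least 500 genes per cell, -0.14 with each library clustered alone, -0.15 in the cells of the merged table and -0.13 without clusters 1 and 19, each with a range that included 0. Neural stem cell genes (-0.48, or -0.11 over members with at least 30 UMIs), cell cycle genes (-0.45), Notch (-0.24) and Wnt (-0.23) signalling, thyroid hormone handling (-0.21), interferon response (-0.20), activated microglia (-0.90), antigen presentation (0.13) and reactive astrocyte genes (0.25) were measured in the same way. Without clusters 1 and 19 several of these medians differed, with -0.28 (-0.59 to 0.05) for neural stem cell genes, -0.25 (-0.62 to 0.08) for cell cycle genes, -0.08 for Wnt signalling, -0.42 (-0.84 to -0.18) for thyroid hormone handling, -0.62 (-1.06 to 0.05) for activated microglia genes, 0.56 (0.10 to 1.05) for reactive astrocyte genes, at percentile 99.02, 0.17 for cholesterol synthesis and 0.28 for heat shock genes. Fto and its neighbours beside the Irx genes had a median of -0.27, and Fto itself 102 and 71 UMIs (-0.50).

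**Figure D4:**
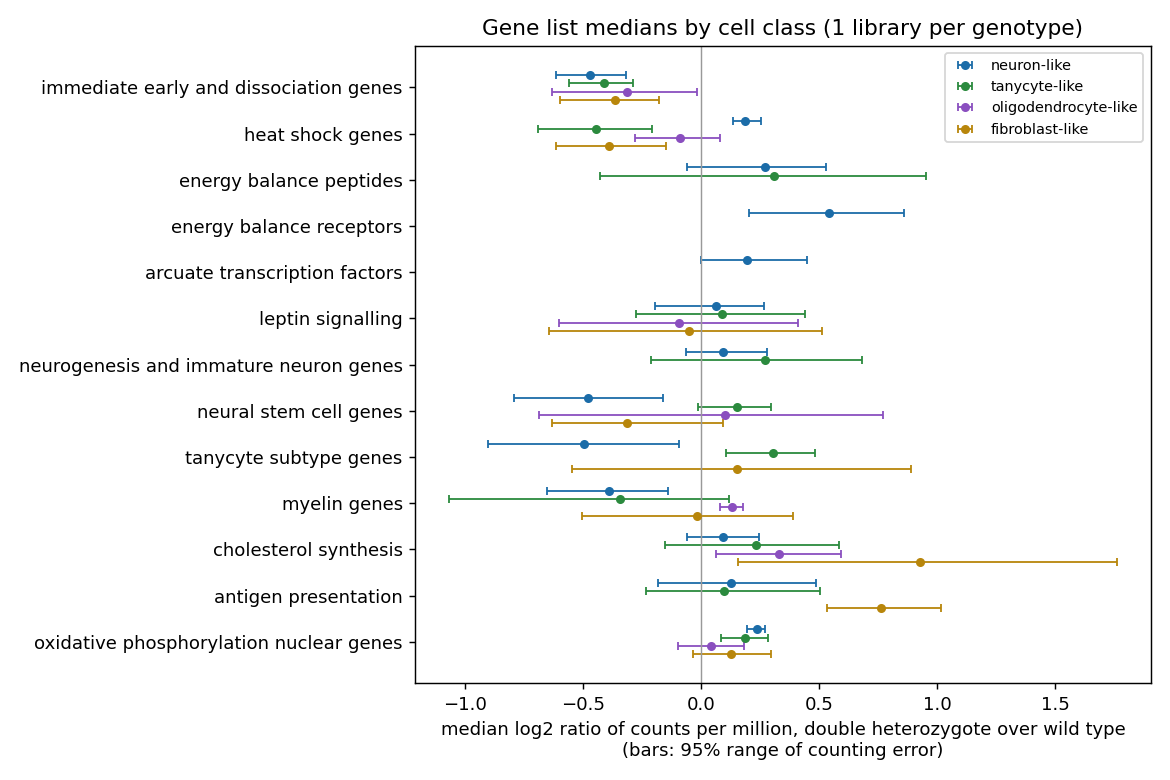
Median log2 ratio of selected fixed gene lists, double heterozygote over wild type (horizontal axis), in the 4 classes compared, with bars for the 95% counting range. Immediate early genes lie below 0 in each class, at -0.47 in neurons, -0.41 in tanycytes, -0.32 in oligodendrocytes and -0.37 in fibroblasts.

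Ranked by the fixed rule, most of the 24 genes named in neurons differed the same way in all other cells. This held for 19 of them, and 9 were pseudogenes. Nme2 (2 and 95 UMIs, fold 48.1, 12.96 to 403), Atp5g1 (174 and 829, 2.27), Cxx1c (57 and 337, 2.58) and Fdx1l (4 and 40, 3.34) were higher, and Sez6 (905 and 147, -2.60), Gm19244 (809 and 147, -2.44), Gm45319 (203 and 16, -3.65) and AC159139.1 (310 and 52, -2.56) lower. Values of pseudogenes, and of genes with near-identical copies, are uncertain, since the counting could split their reads. Oxt, the peptide oxytocin, had 514 and 4228 UMIs (3.06), of which 1021 lay in 1 double heterozygote cell; it was 1.51 with the mean over cells and 3.80 without clusters 1 and 19. Hdc, which makes histamine, had 6 and 54 UMIs (3.19), 36 of them in 1 cell, and 1.52 in the cells of the merged table. Ttr had 631 and 14 UMIs (-5.47), 322 of them in 1 wild type cell, and -0.10 without clusters 1 and 19. By the second ranking, of coding genes not seen to differ alike in other cells, Prph (9 and 46 UMIs, 50% of the latter in 1 cell, 2.37), the dopamine enzyme Th (40 and 118, 1.58), the transforming growth factor receptor Acvr1c (13 and 49, 1.93), Serpina3n (103 and 259, 1.35), Cited1 (359 and 823, 1.22) and Crabp1 (336 and 706, 1.09) were also higher. Nms (116 and 27, -2.08) and Rgs16 (521 and 194, -1.41), genes of the suprachiasmatic nucleus, and Foxb1 (138 and 32, -2.09), a mammillary factor, were lower. Tnnt1 was also lower (41 and 3, -3.75), and Mrps7 (385 and 166, -1.19). Of these, Th, Crabp1, Oxt, Acvr1c, Serpina3n, Cited1, Nms, Rgs16 and Foxb1 were among the leading genes of a neuron-like cluster.

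In tanycytes, immediate early and heat shock genes were lower in the double heterozygote library. Of the tanycyte subtype genes 13 were higher and 3 lower, with a median log2 ratio of 0.30 (0.10 to 0.48) at percentile 96.7, inside the middle 95% of matched lists. It was 0.14 with size factors and 0.14 over members with at least 30 UMIs. The 6 members not used to name tanycytes had the same median. Dio2, which activates thyroid hormone, had 233 and 102 UMIs (0.47), the thyroid hormone transporter Slco1c1 64 and 38 (0.91), and Gpr50 was lower at 172 and 40 (-0.45). Among immediate early genes 2 were higher and 18 lower, with a median of -0.41 (-0.56 to -0.29). It was -0.13 with at least 500 genes per cell and -0.17 with no mitochondrial limit, and -0.22 with own marker scores. Heat shock genes had 4 members higher and 8 lower (median -0.45, -0.69 to -0.21; -0.71 with own marker scores), such as Hspa1a (2054 and 301 UMIs, -1.11) and Dnajb1 (469 and 47, -1.66). Neural stem cell genes were higher in 12 and lower in 6 members, with a median of 0.15 (-0.01 to 0.29) that was -0.01 with size factors, which shifted the median of all tanycyte genes by -0.17. Rax (163 and 54 UMIs, 0.06), Sox2 (245 and 89, 0.20), Nes (105 and 38, 0.19) and Vim (504 and 151, -0.08) differed little, and the Notch target Hes1 was lower (1561 and 310, -0.67). Neurogenesis genes had a median of 0.27, cell cycle genes of 0.15, Notch signalling of 0.27, Wnt signalling of -0.14, thyroid hormone handling of 0.08 (0.37 with the mean over cells) and leptin signalling of 0.09. Of the 4 Hedgehog genes measured, 3 were higher and 1 lower, and the intervals of 2 lay above 0. The higher ones were Ptch1 with 49 and 23 UMIs (0.57), Smo with 16 and 12 (1.24) and Shh with 2 and 10 (3.98). Activated microglia genes (0.47; 0.16 with at least 500 genes per cell), interferon response (0.30), antigen presentation (0.10), reactive astrocyte (-0.28) and astrocyte function genes (0.17; -0.024 with at least 500 genes per cell) were read in the same cells. Ribosomal protein genes had a median of -0.36, and of 0.11 without pseudogenes, and mitochondrially encoded genes -0.45, which was 0.11 with own marker scores and 0.044 over members with at least 30 UMIs. Tanycyte counts came from cluster 2 (306 and 113 cells) and cluster 11 (84 and 53 cells). Cluster 11 held 21.5% (17.6 to 26.0) of wild type and 31.9% (24.9 to 39.6) of double heterozygote tanycytes. Members of the subtype list led each cluster, such as Scn7a and Col25a1 in cluster 11 and Crym and Gpr50 in cluster 2. The tanycyte values therefore do not separate the mix of the clusters from the level within each.

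Of the 24 tanycyte genes named by the fixed rule, 19 differed the same way in all other cells, and 6 were pseudogenes. Those that did not differ alike were Cnmd, Sparcl1, Skil, Gm26772 and Il6. Clec3b, which encodes the plasminogen-binding protein tetranectin, had 35 and 90 UMIs (3.02, 2.44 to 3.63), and 4.39 in the cells of the merged table. Cnmd had 22 and 32 UMIs (2.20, 1.37 to 3.05), Sparcl1 93 and 97 (1.72, 1.29 to 2.14; 2.41 with at least 500 genes per cell), Skil 14 and 18 (2.02), and Cnih2 15 and 26 (2.45; 1.42 with own marker scores). The sodium channel Scn7a had 342 and 251 UMIs (1.21, 0.97 to 1.45), and 0.71 (0.47 to 0.95) within cluster 11, which it leads. Eef1a1 (307 and 261, 1.42) and Gpx4 (89 and 81, 1.52) were higher too, with 1.42 and 1.01 in all other cells. Among the genes lower in the double heterozygote library, Tagln had 34 and 0 UMIs, at least 3.59-fold lower, and Il6, a cytokine, 33 and 0. The Il6 UMIs lay in 4 wild type cells of cluster 11, with 18 in 1 cell, so no fold is read from them. Gm7308 (60 and 0) was at least 6.34-fold lower, Gm19244 had 268 and 10 UMIs (-3.09) and Hsp25-ps1 148 and 5 (-3.23). These are processed pseudogenes, with -1.43, -2.31 and -0.66 in all other cells. By the second ranking, of coding genes not seen to differ alike in other cells, Fbln5, which also leads cluster 11 (46 and 42, 1.53), Itgb5 (37 and 35, 1.58), the retinoid enzyme Lrat (74 and 60, 1.35) and Fabp7, a radial glia protein (25 and 25, 1.66, 0.80 to 2.52), were higher. Other cells held few UMIs of some of these genes, such as 12 and 8 of Lrat, so a like difference there is not excluded. The stress-related genes Atf3 (345 and 33, -1.73), Hspb1 (252 and 22, -1.86), Ier3 (66 and 6, -1.80; 37.9% of the former in 1 cell) and Rgs2 (69 and 4, -2.45) were lower, as was Peg10 (132 and 14, -1.58).

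In oligodendrocytes, Klk6, Hopx and S100b were lower in the double heterozygote library, and Gstp1 was higher. Myelin genes had 13 members higher and 3 lower, with a median of 0.13 (0.08 to 0.18) at percentile 78.5, inside the middle 95% of matched lists. Mal had 2213 and 1187 UMIs (0.48) and the iron carrier Trf 2061 and 599 (-0.40). The 6 members not used to name the class had a median of 0.07, and size factors gave 0.04 for the whole list. Cholesterol synthesis genes were higher in 16 and lower in 4 members (median 0.33, 0.06 to 0.59), such as Msmo1 (103 and 67 UMIs, 0.76). Glycolysis genes had a median of 0.52 (0.17 to 0.99), which was -0.21 over members with at least 30 UMIs. Immediate early genes were lower in 12 of 16 members (-0.32, -0.63 to -0.02), with Fos at 1146 and 264 (-0.74) and Jun at 645 and 114 (-1.12). Klk6, a protease of mature oligodendrocytes, had 145 and 3 UMIs (-4.22, -6.51 to -2.64), and -2.44 with the mean over cells. Hopx had 41 and 0 UMIs, at least 5.26-fold lower, and S100b 486 and 41 (-2.19, -2.69 to -1.73). The Klk6 UMIs lay in 27 of 260 wild type and 2 of 123 double heterozygote cells, and those of Hopx in 25 and 0. For Klk6 and Hopx the values do not separate the number of such cells from the level within each. Gstp1, a detoxifying enzyme, had 439 and 428 UMIs (1.34, 1.15 to 1.54), Tmem163 13 and 20 UMIs and Acsl3 103 and 85 (1.102). Of the 10 genes named by rule, 7 differed the same way in other cells. Among them were S100b (-1.29, -1.49 to -1.09 in other cells) and Gstp1 (1.15, 1.03 to 1.27), but not Klk6 and Hopx. Heat shock genes had a median of -0.09, oxidative phosphorylation genes of 0.04 and ribosomal protein genes of -0.34, or 0.00 without pseudogenes.

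Fibroblast-like cells had higher antigen presentation genes in the double heterozygote library. They were higher in 6 and lower in 1 member, with a median of 0.76 (0.53 to 1.02) at percentile 99.7. B2m had 275 and 321 UMIs (0.70), and the class I genes H2-D1 176 and 226 (0.84) and H2-T23 30 and 45 (1.06). Interferon response genes had a median of 0.43 (0.05 to 0.79) and cholesterol synthesis genes of 0.93 (0.15 to 1.76). Immediate early genes were lower in 17 of 20 members (-0.37, -0.60 to -0.18), heat shock genes in 9 of 12 (-0.39, -0.62 to -0.15). Mgp, a matrix protein also used to name the class, had 1114 and 1878 UMIs (1.23, 1.12 to 1.34), Serpine2 44 and 98 (1.63), Igf2, another naming marker, 21 and 54 (1.84; 35.2% of the latter in 1 cell) and the gap junction gene Gjb6 23 and 53 (1.68; 32.1% of the latter in 1 cell). The chemokine Ccl2 was lower (39 and 5, -2.49), as was Id2 (72 and 24, -1.11). Ptgds (87 and 460 UMIs) and Nnat (28 and 104) were named as higher, but 324 and 90 of these UMIs lay in 1 cell each. With at least 500 genes per cell their log2 ratios were -0.73 and -0.51. Ribosomal protein genes had a median of -0.38, or 0.00 without pseudogenes, and glycolysis genes of 0.48. Of the 10 genes named by rule, 8 differed the same way in other cells.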

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

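All tests of explanations in this part were chosen after the result was seen, except that of depth and the gene minimum per cell and that of fewer UMIs per cell in the double heterozygote library, whose predictions were written before.

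A single cluster passed no fixed cell type and entered no comparison, with 45 wild type and 35 double heterozygote cells. It stood out as signal outside the compared classes. Its cells held the epithelial keratins Krt5 (35 and 40 UMIs) and Krt14 (6 and 27), of which 60% and 40.7% of the double heterozygote UMIs lay in 1 cell, with Cyp2f2 (112 and 121) and Epcam (199 and 93).

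Several gene lists had medians on opposite sides of 0 in different classes, each beyond its counting range in the main setting, and these differences between classes were not tested. Tanycyte subtype genes had a median log2 ratio of -0.50 in neurons and 0.30 in tanycytes. Myelin genes had -0.39 in neurons and 0.13 in oligodendrocytes. Activated microglia genes had -0.90 in neurons and 0.47 in tanycytes, and astrocyte function genes -0.38 and 0.17. In this order, the medians above 0 stood at percentiles 96.7, 78.5, 95.6 and 68.0 of matched lists. The neuron medians stood at percentiles 9.11, 5.37, 1.365 and 0.705. Over all cells together the medians were -0.71, -0.67, 0.09 and -0.54, so values below 0 were not particular to neurons for 3 of these lists. Background from free RNA was not tested for them. Under other settings the ranges of each of these lists included 0, as for myelin genes at 0.042 (-0.0099 to 0.084) in oligodendrocytes and tanycyte subtype genes at 0.14 (-0.07 to 0.32) in tanycytes with size factors, and tanycyte subtype genes at 0.026 in neurons over members with at least 30 UMIs. The same held for activated microglia genes in tanycytes at 0.16 (-0.05 to 0.48) with at least 500 genes per cell and 0.19 (-0.02 to 0.52) with no mitochondrial limit, and in neurons at -0.62 (-1.06 to 0.05) without clusters 1 and 19, and for astrocyte function genes at -0.09 in neurons and -0.024 in tanycytes with at least 500 genes per cell. Heat shock genes had 0.19 in neurons, -0.45 in tanycytes and -0.39 in fibroblasts, with ranges that excluded 0 under each setting. In the main setting these heat shock medians stood at percentiles 93.0, 0.03 and 0.41 of matched lists.

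Processed pseudogenes were lower in the double heterozygote library in each compared class. The class mix is argued against by their median of -0.75 (-0.78 to -0.72) over 2292 genes within neurons. Neurons thinned to 1 depth gave -0.69 (-0.74 to -0.64) over 1190 genes. This cannot decide on fewer UMIs per cell, because random thinning leaves the ratio of scaled sums unchanged on average. Within neurons, fewer UMIs per cell are argued against by the median UMIs, 1569.5 in wild type and 1770 in the double heterozygote, beside the -0.75. Reads of near-identical copies may have been assigned differently in the libraries, since over 152 families the coding genes had a median of 0.23, their copies -0.63 and the sum of both 0.076 (-0.01 to 0.13). A genotype effect on pseudogenes was not tested.

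For the higher neuron share of the double heterozygote library, depth and the gene minimum per cell stay open, since the ratio of 1.58 (1.39 to 1.79) among 2301 cells with at least 1000 UMIs, 35.7% against 56.3%, cannot decide. The prediction was wrong, because this limit left out 40.2% of wild type and 52.5% of double heterozygote cells other than neurons, but 36.8% and 32.7% of neurons, which raises the ratio by itself. More neurons beside an equal mix of other cells is argued against by oligodendrocyte precursors at a ratio of 0.569 (0.419 to 0.763) and fibroblasts at 1.61 (1.26 to 2.05) among 2342 other cells. A different extent of the dissected tissue stays open, as neurons with UMIs of at least 2 suprachiasmatic markers were 12.5% of wild type and 6.53% of double heterozygote neurons, a ratio of 0.523 (0.33 to 0.814), and fewer of them do not raise the neuron share. An effect of the genotype was not tested.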

How the results depend on the processing

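All alternatives reported here were planned before the data were examined, except cells with at least 1000 UMIs, naming without leading genes, neurons without a cluster, all cells without neurons and pseudogenes left out, which were added afterwards. Of 2111 values for 182 results, 2013 stayed within the counting interval or within 1.5 times a count, 82 moved and 16 turned. The cause was not tested except where stated. With at least 500 genes per cell the log2 ratios were -0.73 for Ptgds and -0.51 for Nnat in fibroblasts, and the tanycyte medians -0.024 for astrocyte function genes and -0.13 for immediate early genes. With no mitochondrial limit the last was -0.17. With classes from each cell's own marker score the neuron share ratio was 1.56, Ttr 0.61 in neurons, Nnat -1.11, the peptide median in neurons -0.13, and in tanycytes immediate early genes -0.22 and mitochondrial genes 0.11. Nnat was -0.43 with each library clustered alone and -0.43 in the cells of the merged table. Size factors gave -0.014 for neural stem cell and -0.58 for immediate early genes in tanycytes and 0.042 for myelin genes in oligodendrocytes, and shifted the median of all genes by -0.17 in tanycytes and -0.13 in fibroblasts. The mean over cells gave -0.20 for leptin signalling in neurons. Members with at least 30 UMIs gave 0.026 for tanycyte subtype genes in neurons, 0.044 for mitochondrial genes in tanycytes and -0.21 for glycolysis in oligodendrocytes. Naming without leading genes gave tanycyte share ratios of 0.983 with at least 500 genes per cell and 1.02 with separate clustering, as the larger tanycyte cluster was then named astrocyte-like. Cells with at least 1000 UMIs gave ratios of 1.58 for neurons, 0.266 for oligodendrocyte precursors and 0.527 for tanycytes. Without pseudogenes, ribosomal protein medians were 0.19 in neurons, 0.11 in tanycytes, 0.0034 in oligodendrocytes and 0.0045 in fibroblasts. Neuron share ratios ranged from 1.32 to 1.58, Agrp share ratios up to 3.61 and receptor medians in neurons from 0.49 to 0.75 over the alternatives. Naming genes with at least 100 UMIs kept 14 of 24 genes in neurons, 10 of 24 in tanycytes, and 4 of 10 in oligodendrocytes and in fibroblasts. No paired analysis was possible because each genotype had 1 pooled library. Irx3 and Irx5 were limited by depth, with folds of 0.642 to 1.15 and 0.461 to 1.05.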

Other observations

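The tests of Agrp and Npy at the end of this part, and the macrophage marker split, were chosen after the result was seen.

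Microglia-like cells, the immune cells of the brain, were too few for the main comparisons (106 wild type and 46 double heterozygote cells). Homeostatic genes were lower in the double heterozygote library in 12 of 12 members, with a median log2 ratio of -0.82 (-1.02 to -0.65). P2ry12 had 328 and 83 UMIs (-0.90) and Gpr34 146 and 22 (-1.65), and part of this list also named the class. Activated microglia genes had a median of 1.57 (0.72 to 2.07), with Apoe at 501 and 1448 UMIs (2.62), and antigen presentation genes 1.501 (1.27 to 1.75), with B2m at 368 and 263 (0.60). Immediate early genes, lower in the 4 compared classes, were higher in microglia (0.82, 0.49 to 1.15). Cells with UMIs of at least 2 perivascular macrophage markers were 2 of 106 (1.89%, 0.229 to 6.65) in wild type and 8 of 46 (17.4%, 7.82 to 31.4) in the double heterozygote. Without them the medians were -0.53 for homeostatic, 1.64 for activated and 1.49 for antigen presentation genes.

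Oligodendrocyte precursor-like cells (210 and 59) had a median of 0.54 (-0.09 to 0.998) for immediate early genes and 0.48 for myelin genes. Ependymal-like cells (137 and 73) had -0.77 (-1.17 to -0.43) for immediate early genes, and their Clec3b had 87 and 120 UMIs.

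Agrp and Npy were found in more neurons of the double heterozygote library. For Agrp, free RNA is argued against by neurons with at least 3 Agrp UMIs after thinning, 6.11% (4.13 to 8.65) of 475 in the double heterozygote and 1.54% (0.665 to 3.003) in wild type. Free RNA of Npy was not tested. Npy was also higher in all cells other than neurons, with 66 and 58 UMIs (log2 ratio 1.11, 0.58 to 1.64). More of the whole arcuate nucleus in the dissection may account for the higher shares of Agrp and Npy, and cannot be told apart from an effect of the genotype. Against neurons with Pomc, Tac2 or Kiss1, the odds ratio was 1.35 (0.715 to 2.58) in another random draw of the thinning than that of the shares in the report, leaving out 2 wild type and 7 double heterozygote neurons with both kinds of peptide. It rested on 28 and 49 neurons with Agrp or Npy only and 48 and 62 with the other peptides only, too few to decide.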
